A study of Homo sapiens with 7 samples.

How the data were processed

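Gene expression was measured by bulk RNA sequencing in SH-SY5Y cells, a human neuroblastoma line of sympathetic lineage that is widely used as a model of catecholaminergic neurons. Per the labels' protocols, the cells were exposed to siRNA for 2 to 3 days, RNA was extracted with ISOGEN II, and the libraries were made for the DNBSEQ platform. The siRNAs were a control, one against estrogen-related receptor α (ERRα, gene ESRRA), one against estrogen-related receptor γ (ERRγ, gene ESRRG), and both together. The 7 libraries came in 2 sets. Set 1 (molecule label total RNA) held 3 libraries: control, ERRα siRNA and ERRγ siRNA. Set 2 (molecule label polyA RNA) held 4 libraries: the same conditions and the double knockdown. Each condition had 1 library per set. In the table of set 2, column names gave the condition and were matched to the groups by that name. Nothing in the labels says how cultures were separated beyond the sets, so the p-values measure only the spread between these libraries, part of which may be technical.

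The authors deposited TPM values (a relative transcript abundance scaled for transcript length and library size), in a separate table for each set. The submitters' processing notes name STAR 2.7.10a and the genome build hg38. The program that made the TPM values and its annotation are not given in the sources used here. Both tables held 19942 lines with 19924 distinct Ensembl gene identifiers, the same in both; 18 identifiers stood on 2 lines, with values of 0 throughout, and were kept once. Symbols came from a gene name table for 19892 identifiers, and positions, transcript lengths and GC content from GENCODE 29 on hg38. The tables listed protein-coding genes almost throughout (19770 in GENCODE 29), and 0 genes of the mitochondrial genome. The listed TPM summed to between 61.6% and 64.8% of the full scale of the unit in set 1 and to between 78.7% and 80.2% in set 2. TPM keeps no sequencing depth, so the depth per library is unknown and no counting interval is given. Between 11813 and 12523 genes reached 1 TPM per library.

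Values were analysed as log2(TPM + 1), so a fold change understates the change of genes with low TPM. Because the tables were made separately, the model compared libraries within sets and combined the differences. A linear model with a set term and a group term was fitted to all 7 libraries with limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean-variance trend), over 12690 genes with at least 1 TPM in at least 2 libraries. The model had 2 residual degrees of freedom and a prior of 3.75. The double knockdown had 1 library and was assumed to vary like the other groups. Its fitted values rest on a control level of set 2 that the model estimated with the help of set 1. They and their list tests can therefore differ from the plain difference in set 2. LMNA, for example, was fitted at -3.15 against a plain -2.62. Comparisons of the double knockdown with the single ones share this. Contrasts were each knockdown against control, ERRα against ERRγ siRNA, and the double knockdown against the sum of the single ones. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. In the text, values with ± are limma's fitted log2 fold changes with their standard error, and values for a set are plain differences from the control library of that set, without an error of their own.

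Of 39 gene lists fixed before the data were examined, 34 had at least 5 tested genes. They were tested with limma's camera at a preset correlation of 0.01, adjusted over 102 tests (34 lists and 3 knockdowns), and separately over 68 tests for the contrasts between knockdowns. Camera was also run with an estimated correlation, and limma's fry, which asks whether the genes of a list move one way on balance and does not compare them with other genes, was run beside it. Within each set, the median of a list was placed among 10000 random lists of the same size matched on mean expression. Correlations of fold changes across genes were computed with numpy 2.4.6 and pandas 2.3.3 in Python 3.11.15, and figures with matplotlib 3.10.9. Genes are not independent replicates, so no p-value was given for them. For fold changes that share a control library, the correlation of simulated unchanged groups is printed beside the observed one.

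The design, the tests, the gene lists, the rule for named genes and the alternatives were chosen before the data were examined, except where the text says otherwise. Named were ESRRA, ESRRB and ESRRG; for each single knockdown the 10 highest and 10 lowest genes by the smaller of the fold changes of both sets, among genes with the same sign in both and a mean of at least 5 TPM; for the double knockdown the 10 highest and 10 lowest in set 2; up to 4 members of each list with the largest fitted change; and up to 10 genes with the smallest adjusted p in the contrasts between knockdowns. Some genes that this rule selects are not reported here. Alternatives were other pseudocounts, other filters on low values, median centring, a rescaling without ribosomal protein genes, quantile normalization, no set term, no trend, and each library left out in turn. A robust form of the empirical Bayes step was added after the data were seen. A library is said to stand apart in a gene where it lay at least 2-fold from every other library of its set while those lay within 0.5 of each other on the log2 scale, a definition also chosen then.

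The gene model was tested on simulated data with 200 changed genes among 12690, in 5 draws per comparison. The changed genes were split equally among 2-, 4-, 8- and 16-fold changes. The model recovered 50.4% of genes changed 2-fold with ERRα siRNA, 51.2% with ERRγ siRNA and 24.4% with both. Of genes changed 4-fold it recovered 92.8%, 94% and 82.8%. The many large changes loosen the Benjamini-Hochberg cutoff, so these shares do not carry over to data with few changed genes. In the data, ESRRA with ERRα siRNA, fitted at -1.47 ± 0.14, did not pass (limma, adjusted p = 0.705). Camera recovered a list shifted by 0.5 on the log2 scale in 15 of 15 draws, with 1 other list called. The simulated genes varied independently, so this does not test camera on lists whose genes vary together. The shift was also larger than the fitted median of every list called below, other than histone genes.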

Results

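The data were 7 transcriptomes of SH-SY5Y neuroblastoma cells in which the orphan nuclear receptors ERRα and ERRγ, regulators of mitochondrial and oxidative metabolism, were depleted by siRNA. Set 1 held a control, an ERRα siRNA and an ERRγ siRNA library. Set 2 held the same conditions and a library in which both receptors were targeted. Each condition therefore had at most 2 libraries, and the double knockdown had no replicate. Within a set, log2 values of any pair of libraries correlated across genes with r between 0.975 and 0.991. Between sets, r lay between 0.915 and 0.939.

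The targeted transcripts were lower in every library that received their siRNA. ESRRA (ENSG00000173153, chromosome 11, 64305572 to 64316743, hg38) was listed at 20.9 TPM in the control of set 1 and at 6.03 TPM with ERRα siRNA, 28.9% of control. In set 2 it was 42.8 TPM in the control, 16.9 TPM with ERRα siRNA (39.5%) and 17.8 TPM in the double knockdown (41.5%). ESRRG (ENSG00000196482, chromosome 1, 216503246 to 217137755, hg38) was 8.34 TPM in the control of set 1 and 3.66 TPM with ERRγ siRNA (43.9%). In set 2 it was 22.7 TPM in the control, 8.58 TPM with ERRγ siRNA (37.8%) and 11.1 TPM in the double knockdown (49.1%). The other receptor was not lowered as far: ESRRA was at 77.2% and 84.9% of control with ERRγ siRNA, and ESRRG at 171% and 107% with ERRα siRNA. ESRRB, the remaining family member, was at most 0.145 TPM in any library. The fitted change of ESRRA with ERRα siRNA was -1.47 ± 0.14 (limma, adjusted p = 0.705), and that of ESRRG with ERRγ siRNA was -1.15 ± 0.19 (limma, adjusted p = 0.27), so neither passed the threshold over all genes.

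**Figure D1:**
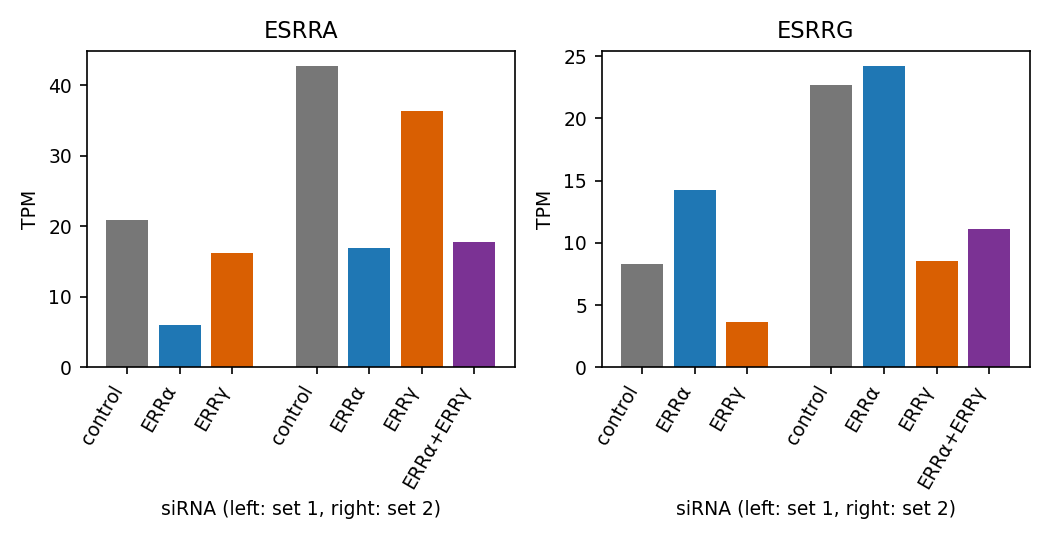
TPM of ESRRA and ESRRG in each of the 7 libraries, set 1 at the left and set 2 at the right of each panel; each bar is 1 library. ESRRA was 6.03 TPM and 16.9 TPM with ERRα siRNA against 20.9 TPM and 42.8 TPM in the controls, and ESRRG was 3.66 TPM and 8.58 TPM with ERRγ siRNA against 8.34 TPM and 22.7 TPM.

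With ERRα depleted, p53 target genes were higher as a group by camera. Replication-dependent histone genes, retinoic acid response genes and fatty acid synthesis genes were lower. These calls held only at the preset correlation. Those for retinoic acid and fatty acid synthesis genes were also lost when single libraries were left out. The cyclin-dependent kinase inhibitor CDKN1A was 45.8 TPM in the control and 83.7 TPM with ERRα siRNA in set 1, and 61.6 and 84.2 TPM in set 2 (fitted 0.65 ± 0.13). The stress cytokine GDF15 differed by 0.61 and 0.52 in sets 1 and 2, the RNA-binding growth inhibitor ZMAT3 by 0.70 and 0.29, and the death receptor TNFRSF10B by 0.42 and 0.30. Of 24 p53 targets tested, 16 were higher in both sets and 0 were lower in both. In the double knockdown 15 were higher and 9 lower, with a set 2 median of 0.18, and the list did not pass. With ERRα siRNA the median was 0.22 (0.16 in set 1, 0.24 in set 2; camera adjusted p = 1.83e-07; adjusted p = 0.796 with an estimated correlation). Without the ERRα library of set 2 this median was 0.14 (camera adjusted p = 9.48e-05).

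Among 10 replication-dependent histone genes, 9 were lower in both sets with ERRα siRNA, with a median of -0.38 (-0.27 in set 1, -0.53 in set 2; camera adjusted p = 2.07e-05; adjusted p = 0.868 with an estimated correlation). Set 2 was labelled polyA RNA, so its histone values, here and below, cover polyadenylated transcripts only. They do not measure the whole histone transcript pool. H2AC6 differed by -0.66 and -0.61, the linker histone H1-2 by -0.88 and -0.39, and H2BC12 by -0.31 and -0.67; H2BC4, at a mean of 1.02 TPM, differed by -0.77 and -0.65. Without the control library of set 2, the histone median was -0.19 (camera adjusted p = 0.0487), and with a pseudocount of 5 it was -0.26. Retinoic acid response genes (10 tested, 6 lower in both sets) had a median of -0.26 (camera adjusted p = 0.000487; adjusted p = 0.868 with an estimated correlation). Their members CRABP2, a carrier of retinoic acid to the nucleus, differed by -0.49 and -0.91, the retinol transporter STRA6 by -0.41 and -0.23, the homeobox gene HOXD4 by -0.50 and -0.38, and the transglutaminase TGM2, at a mean of 1.16 TPM, by -0.86 and -0.75. This call was lost without the control library of set 1 (camera adjusted p = 0.134, median -0.26), and with genes of low TPM kept the median was -0.12 (camera adjusted p = 0.046). Fatty acid synthesis genes (13 tested, 9 lower in both sets) had a median of -0.14 (camera adjusted p = 0.00883; adjusted p = 0.868 with an estimated correlation). In the double knockdown 9 of the 13 were higher and 4 lower, with a set 2 median of 0.069. With ERRα siRNA, ACACA, the enzyme that makes malonyl-CoA, differed by -1.52 and -0.27, with the control library of set 1 apart. The elongase ELOVL1 differed by -0.17 and -0.23, and the desaturases FADS2 and SCD by -0.29 and -0.10 and by -0.28 and -0.09. The call was lost without the control library of set 1 (camera adjusted p = 0.293, median -0.083), without either ERRα library (0.0526 with a median of -0.095 and 0.0707 with a median of -0.18) and with no set term (0.0744).

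Ranked by the smaller of the values of both sets, the genes furthest above control with ERRα siRNA included TTLL5, a tubulin polyglutamylase (1.44 in set 1 and 1.24 in set 2), HIP1, an endocytic adaptor (1.89 and 0.84), the scaffold ANK2 (1.54 and 0.69), EZH1, a Polycomb histone methyltransferase (0.82 and 0.88), DENND2B (0.90 and 0.94), HS6ST2 (0.81 and 0.99), GAS2L3 (0.79 and 0.80) and SH3BP2 (0.91 and 0.75). AP2M1, the medium subunit of the clathrin adaptor of the plasma membrane, was 203 TPM in the control and 322 TPM with ERRα siRNA in set 1, and 179 and 281 TPM in set 2. The Wnt antagonist DKK1 was also among them (0.75 and 1.00). Lowest after ESRRA were SMUG1, a uracil DNA glycosylase (-1.93 and -1.01), the zinc importer SLC39A4 (-0.998 and -2.57), CCDC57 (-1.03 and -0.95), CCZ1B (-0.98 and -0.76), PHKB (-1.22 and -0.69), C3orf14 (-1.005 and -0.76), CLIP4 (-0.76 and -0.72), TGFB1 (-0.71 and -0.64) and the water channel AQP1 (-0.64 and -0.64). CCZ1B has a near-identical copy, CCZ1, and its value depends on how shared reads were assigned. In the double knockdown, which also received ERRα siRNA, TTLL5 (0.008), HIP1 (-0.003), DENND2B (0.17), C3orf14 (0.18) and CLIP4 (-0.099) changed little or turned. The other genes named here kept their direction there. With ERRγ siRNA, CCZ1B (-0.96 and -0.81), SMUG1 (-0.58 and -0.36), CCDC57 (-0.73 and -0.39), PHKB (-0.39 and -1.105), SLC39A4 (-1.675 and -0.067) and AQP1 were also lower in both sets. TTLL5 (0.285 and 1.04), GAS2L3 (0.55 and 0.83), ANK2 (0.90 and 0.45), EZH1 (0.24 and 0.71) and DKK1 were also higher in both. DENND2B, HIP1, HS6ST2, SH3BP2, AP2M1, C3orf14, CLIP4 and TGFB1 had opposite signs in the sets. Both siRNAs were compared with the same controls, so shared changes may come from them. With ERRα siRNA, none of the 12690 genes passed the threshold (limma, 0 genes; 547 at an unadjusted p under 0.05, where 634 are expected by chance; 0 genes also with the robust form). Without the control library of set 2 limma called 9 genes, and without the control library of set 1 it called 1.

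ERRα is known as a regulator of energy metabolism, and lists of such genes were tested for this reason. The 37 textbook ERR target genes had a median of -0.027 with ERRα siRNA (camera adjusted p = 0.573), -0.072 with ERRγ siRNA (0.0974) and -0.048 in the double knockdown (0.167). TCA cycle genes were at -0.070 with ERRα siRNA (0.0544). Subunits of complexes II to IV with cytochrome c were at -0.086 with ERRγ siRNA (0.0544). None of these passed the threshold.

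With ERRγ depleted, cell cycle genes were higher by camera and genes for both cytosolic and mitochondrial ribosomes were lower. These calls held only at the preset correlation. The S phase and both ribosomal calls were also lost when single libraries were left out. G2 and M phase genes had a median of 0.36 (0.29 in set 1, 0.41 in set 2), and 36 of 43 were higher in both sets (camera adjusted p = 4.02e-13; adjusted p = 0.796 with an estimated correlation). The spindle protein ASPM differed by 1.76 in set 1 and 0.51 in set 2, the mitotic hyaluronan receptor HMMR by 1.23 and 0.62, the checkpoint kinase TTK by 1.19 and 0.37, and the kinetochore protein CENPF by 1.22 and 0.25. For 19 of the 43, limma's p passed when adjusted over the list alone, and for 0 when adjusted over all genes. S phase genes had a median of 0.27 (0.13 in set 1, 0.33 in set 2; 27 of 39 higher in both sets; camera adjusted p = 3.22e-07; adjusted p = 0.868 with an estimated correlation). The clamp loader subunit RFC4 differed by 0.43 and 1.05, the ribonucleotide reductase subunit RRM2 by 0.45 and 0.79, the transcription factor E2F1 by 0.34 and 0.56, and the replication checkpoint adaptor CLSPN by 0.58 and 0.30. Without the ERRγ library of set 2 the S phase call was lost (camera adjusted p = 0.224, median 0.17), and without the control library of set 2 its median was 0.14 (camera adjusted p = 0.0252). A trend of fold change with gene length, GC content and expression level held 20.8% of the variance in the ERRγ library of set 1 and 2.7% in that of set 2. With the trend removed, the G2 and M phase medians were 0.18 and 0.41, and the S phase medians 0.074 and 0.31.

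Cytosolic ribosomal protein genes had a median of -0.13 with ERRγ siRNA (-0.18 in set 1, -0.089 in set 2), and 47 of 74 were lower in both sets (camera adjusted p = 2.7e-07; adjusted p = 0.868 with an estimated correlation). Mitochondrial ribosome genes had a median of -0.11 (-0.15 in set 1, -0.059 in set 2), with 44 of 75 lower in both sets (camera adjusted p = 4.89e-05; adjusted p = 0.868 with an estimated correlation). RPL34 differed by -0.18 and -0.79, RPS15A by -0.86 and -0.01, MRPL34 by -0.47 and -0.41, MRPS34 by -0.86 and -0.19 and MRPL21 by -0.96 and -0.16. RPL9 differed by -0.04 and -1.21, and its control library of set 2 stood apart from the rest of the set. MRPL23 differed by -1.67 and -0.09, and its ERRγ library of set 1 stood apart. Both calls were lost without the ERRγ library of set 1 (camera adjusted p = 0.121 with a median of -0.079 for cytosolic, 0.0874 with a median of -0.086 for mitochondrial ribosome genes), and the mitochondrial median was -0.069 without the control library of set 1. Quantile normalization left the cytosolic median at -0.056 and median centring the mitochondrial one at -0.16, both past the threshold (camera adjusted p = 0.0222 and 8.13e-05).

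NRF2 antioxidant genes fell with ERRγ siRNA, with 15 of 20 lower in both sets and a median of -0.17 (camera adjusted p = 6.02e-05; adjusted p = 0.868 with an estimated correlation); it was -0.29 without the ERRγ library of set 2. The quinone reductase NQO1 was 15.7 TPM in the control and 8.41 TPM with ERRγ siRNA in set 1, and 21.9 and 13.0 TPM in set 2. The aldo-keto reductase AKR1C3 differed by -1.90 and -0.83, the heme oxygenase HMOX1 by -1.09 and -0.37 and OSGIN1 by -0.24 and -0.90; AKR1C3 has close paralogs that can share its reads. Of the 20 genes, 1 passed limma's test adjusted over the list alone and 0 adjusted over all genes. Replication-dependent histone genes fell, with 9 of 10 lower in both sets and a median of -0.59 (-0.28 in set 1, -0.70 in set 2; camera adjusted p = 6.06e-05; adjusted p = 0.868 with an estimated correlation). They were lower with ERRα siRNA too, against the same controls, and the list did not differ between the knockdowns (median 0.158, camera adjusted p = 0.262). H2AC6 differed by -0.89 and -1.26, H2BC12 by -0.36 and -1.43, H1-2 by -1.12 and -0.50 and H2BC4 by -0.59 and -0.81, and 4 of the 10 passed limma's test adjusted over the list alone. The histone median was -0.33 without the control library of set 2, -0.37 without the ERRγ library of set 2, -0.33 with a pseudocount of 5 and -0.27 with genes of low TPM kept. Genes of the unfolded protein response of the endoplasmic reticulum rose, with 16 of 23 higher in both sets and a median of 0.21 (0.28 in set 1, 0.083 in set 2; camera adjusted p = 0.00759; adjusted p = 0.868 with an estimated correlation). EDEM1, which acts in the disposal of misfolded proteins, differed by 1.13 and 0.28, and CRELD2 by 0.28 and 0.51. The chaperone partners DNAJC3 and DNAJB9 differed by 0.80 and 0.16 and by 0.86 and -0.04. The call was lost without the ERRγ library of set 1 (camera adjusted p = 0.377, median 0.066) and without the control library of set 1 (0.0514), and the median was 0.32 without the ERRγ library of set 2.

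Among single genes, DKK1 was 41.3 TPM in the control and 155 TPM with ERRγ siRNA in set 1, and 71.0 and 184 TPM in set 2 (fitted 1.62 ± 0.18; limma, adjusted p = 0.258). ANGPTL4, a secreted inhibitor of lipoprotein lipase, was 7.55 and 20.4 TPM in set 1 and 6.63 and 19.9 TPM in set 2 (fitted 1.39 ± 0.15; limma, adjusted p = 0.258). Also higher in both sets were the actin-binding protein ENC1 (1.48 and 1.15), PUDP (1.37 and 1.15), DOP1A (1.04 and 1.33), the nicotinic receptor subunit CHRNB4 (1.01 and 1.22), MAN1A1 (0.96 and 0.97), the transcription factor CREB5 (0.93 and 2.04), the lysyl oxidase LOXL2 (0.90 and 0.92) and the tropomyosin TPM1 (1.18 and 0.89). Lower in both sets was the secreted factor SERPINF1, at 37.3 TPM in the control and 14.1 TPM with ERRγ siRNA in set 1, and 111 and 46.4 TPM in set 2. Lower beside it were the hedgehog co-receptor BOC (-1.62 and -1.39), the metalloproteinase inhibitor TIMP3 (-1.35 and -1.25), AQP1 (-1.10 and -1.29), the sphingosine phosphate receptor S1PR3 (-1.07 and -1.19), the galectin LGALS3 (-1.06 and -1.08), EHD3 (-1.33 and -1.005) and LRRN1 (-1.003 and -1.42). In the double knockdown, which also received ERRγ siRNA, CHRNB4 turned (-1.03), and DOP1A (0.13) and BOC (-0.245) changed less. The other genes named here kept their direction there. With ERRα siRNA, CHRNB4 (1.91 and 0.46), PUDP (0.63 and 0.345), DKK1, ENC1, DOP1A and MAN1A1 were also higher in both sets. SERPINF1 (-0.89 and -0.53), TIMP3 (-0.32 and -0.42), LGALS3 (-0.45 and -0.375), AQP1, S1PR3 and BOC were also lower in both. EHD3 was slightly higher in both (0.094 and 0.079), and ANGPTL4, CREB5, LOXL2, TPM1 and LRRN1 had opposite signs in the sets. Both siRNAs were compared with the same controls, so shared changes may come from them. With ERRγ siRNA, no gene passed the threshold (limma, 0 of 12690; 1764 at an unadjusted p under 0.05, where 634 are expected by chance; 0 genes also with the robust form). Without the control library of set 2 limma called 13 genes, and without the control library of set 1 it called 1.

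**Figure D2:**
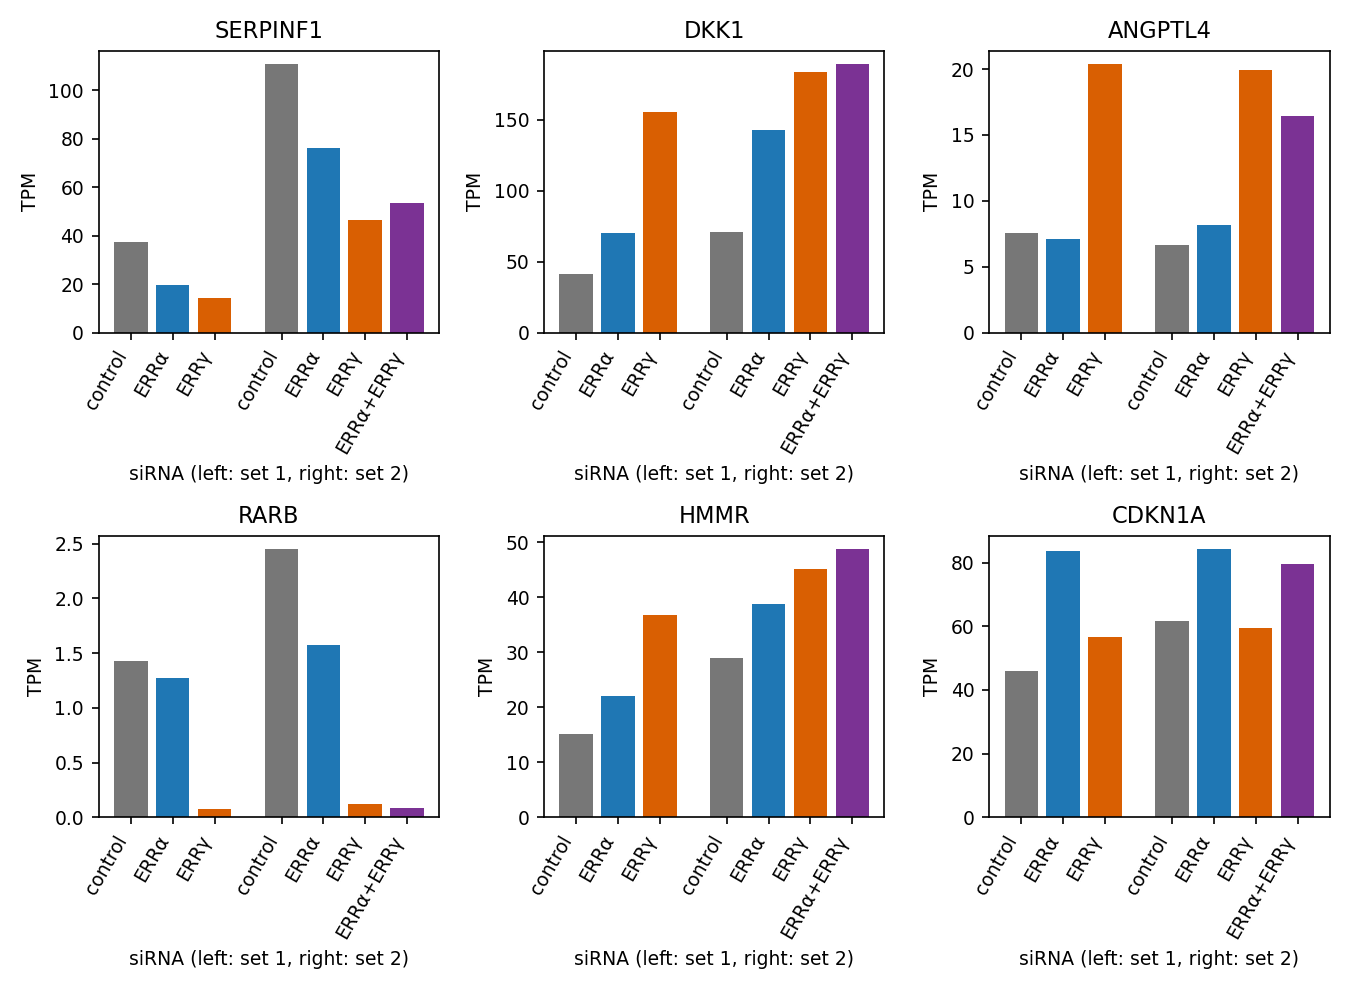
TPM of SERPINF1, DKK1, ANGPTL4, RARB, HMMR and CDKN1A in each library, set 1 at the left and set 2 at the right of each panel; each bar is 1 library. SERPINF1 was 14.1 TPM and 46.4 TPM with ERRγ siRNA against 37.3 TPM and 111 TPM in the controls, while CDKN1A was 83.7 TPM and 84.2 TPM with ERRα siRNA against 45.8 TPM and 61.6 TPM.

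With both receptors targeted, cell cycle genes were again higher by camera, and histone, ribosomal, complex I and ATP synthase genes were lower. These calls held only at the preset correlation. The ATP synthase call was also lost when single libraries were left out, and the cytosolic ribosomal call with quantile normalization. Camera's p-values are for the fitted changes, which also draw on set 1. All 43 G2 and M phase genes were higher than in the control of set 2, with a median of 0.42 in that set (camera adjusted p = 9.15e-15; adjusted p = 0.796 with an estimated correlation), and 38 of 39 S phase genes were higher, with a median of 0.37 (camera adjusted p = 9.86e-13; adjusted p = 0.868 with an estimated correlation). ASPM differed by 0.77, HMMR by 0.73, the kinetochore motor CENPE by 0.79, KIF23 by 0.65, RFC4 by 0.87, RRM2 by 0.79, GINS1 by 0.67 and E2F1 by 0.64. Of 10 histone genes, 9 were lower, with a median of -0.78 in set 2 (camera adjusted p = 2.7e-07; adjusted p = 0.868 with an estimated correlation), and 5 passed limma's test adjusted over the list alone; H2AC6 differed by -1.10 and H2BC21 by -1.25. The fitted histone median, -0.70, was -0.41 with a pseudocount of 5, -0.44 with genes of low TPM kept and -0.31 with no set term. With no set term the fitted G2 and M phase and S phase medians, 0.37 and 0.31, were 0.61 and 0.52.

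Smaller shifts were seen in complex I, ATP synthase, ribosomal, retinoic acid and NRF2 lists of the double knockdown, each with adjusted p = 0.868 with an estimated correlation. Complex I genes had a median of -0.085 in set 2 (27 of 37 lower; camera adjusted p = 0.00158), with NDUFC1 at -0.70 and NDUFA13 at -0.32. ATP synthase genes were at -0.081 (12 of 18 lower; camera adjusted p = 0.0171), with ATP5ME at -0.38, ATP5F1E at -0.33 and ATP5PD at 0.006 (fitted 0.31). Subunits of complexes II to IV with cytochrome c did not pass (median -0.059, 16 of 26 lower; camera adjusted p = 0.147). Cytosolic ribosomal protein genes were at -0.061 (53 of 74 lower; camera adjusted p = 2.68e-05) and mitochondrial ribosome genes at -0.062 (46 of 75 lower; camera adjusted p = 0.00158). MRPS12 differed by -0.36, MRPL19 by 0.37 and MRPL27 by -1.45, with the double knockdown library apart. Retinoic acid response genes were at -0.13 (7 of 10 lower; camera adjusted p = 0.00214; adjusted p = 0.868 with an estimated correlation), with the retinoic acid receptor RARB at 2.45 TPM in the control and 0.0841 TPM in the double knockdown, and CRABP2 at 159 and 66.0 TPM. NRF2 antioxidant genes were at -0.071 (11 of 20 lower; camera adjusted p = 0.00886; adjusted p = 0.868 with an estimated correlation), with AKR1C3 at -0.68 and NQO1 at -0.41. Quantile normalization ended the call for cytosolic ribosomal proteins (camera adjusted p = 0.592, fitted median -0.005). Leaving out the control library of set 1 ended the calls for ATP synthase (0.102) and NRF2 genes (0.165), as did leaving out the ERRγ library of set 1 (0.085 and 0.0582), and ATP synthase was also lost without the ERRγ library of set 2 (0.0589). Without the control library of set 2, the fitted NRF2 median was -0.19 and that of complex I was -0.12, against -0.067 and -0.077 over all libraries; with genes of low TPM kept, the retinoic acid median was -0.093 against -0.17. Centring the medians took the fitted medians of complex I, ATP synthase, cytosolic and mitochondrial ribosome genes to -0.14, -0.16, -0.14 and -0.14 and that of NRF2 genes to -0.13, which was -0.040 with genes of low TPM kept and -0.042 with no set term. Quantile normalization took those of complex I and mitochondrial ribosome genes to -0.12 and -0.13. With no set term the medians of complex I, ATP synthase, cytosolic and mitochondrial ribosome genes turned to 0.143, 0.051, 0.172 and 0.112, where the median of all genes was 0.35, and the ATP synthase call was lost (camera adjusted p = 0.101).

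**Figure D3:**
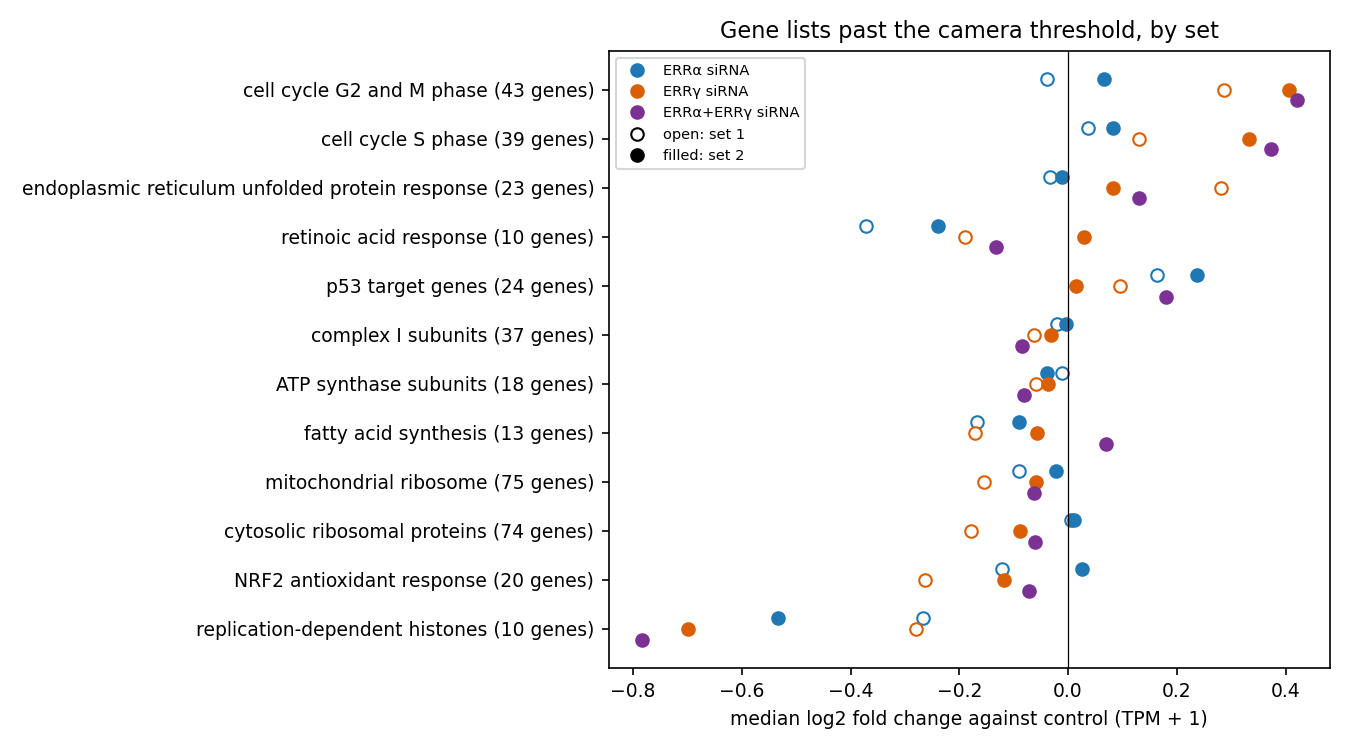
Median log2 fold change, on the log2(TPM + 1) scale, of each gene list that passed the camera threshold in at least 1 knockdown, with open circles for set 1 and filled circles for set 2. G2 and M phase genes lay at 0.29 and 0.41 with ERRγ siRNA and at 0.42 in the double knockdown, against -0.038 and 0.066 with ERRα siRNA.

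Single genes of the double knockdown have no replicate. The highest against the control of set 2 were the alanyl-tRNA synthetase AARS1 (1.72), KANSL1 (1.66), TXNRD2 (1.64), FRMD4A (1.52), CENPT (1.42), DKK1 (1.40), GBF1 (1.37), ADGRL2 (1.36), EXOSC8 (1.34) and ZCWPW1 (1.33). The lowest included the nuclear lamin LMNA, at 109 TPM in the control and 17.0 TPM with both siRNAs (-2.62), SLC39A4 (-2.21), PRCD (-2.02), ZNF814 (-1.52), RPL9 (-1.47), MRPL27 (-1.45), H2BC12 (-1.35), RHBDD1 (-1.33) and PGS1 (-1.30). In several of these a lone library stood apart from the rest of set 2: the double knockdown in CENPT, EXOSC8, LMNA, ZNF814 and MRPL27, and the control in TXNRD2, GBF1 and RPL9. TXNRD2 was 8.35 TPM in that control against 24.5, 27.3 and 28.1 TPM in the other libraries of the set. LMNA in set 1 was 121 TPM in the control and 38.0 and 38.5 TPM with ERRα and ERRγ siRNA, so a library stood apart in each set. By the rule of at least 2-fold, 77 genes were higher and 102 lower. No gene passed limma's threshold (0 of 12690; 837 at an unadjusted p under 0.05, where 634 are expected by chance; 0 genes also with the robust form). Without the control library of set 1 limma called 1 gene, and LMNA had an adjusted p of 0.0114; without the control library of set 2 it called 2, and LMNA had an adjusted p of 0.00119. PGS1 changed sign without the control library of set 2 (0.40).

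The single knockdowns were compared directly to find transcripts that differ between the ERRα and ERRγ siRNAs. The design cannot tell a response to loss of a receptor from another effect of its siRNA. SH3BGRL was lower with ERRγ than with ERRα siRNA by a log2 difference (ERRα minus ERRγ) of 1.11 ± 0.11. The imprinted gene RTL1 (-1.002 ± 0.097), the nicotinic receptor subunit CHRNA3 (-0.86 ± 0.09), ANGPTL4 (-1.30 ± 0.15), the hypoxia-inducible factor EPAS1 (-1.85 ± 0.22), COCH (-1.18 ± 0.14) and the small GTPase RHOA (-1.06 ± 0.11) were lower with ERRα than with ERRγ siRNA. Against control, RTL1 (-0.32 and -0.06), CHRNA3 (-0.053 and -0.046) and ANGPTL4 (-0.08 and 0.26) differed less with ERRα siRNA than with ERRγ siRNA, where they rose. EPAS1 and COCH were lower than control with ERRα siRNA and higher with ERRγ siRNA in both sets. RHOA was 337 TPM in the control, 192 TPM with ERRα and 451 TPM with ERRγ siRNA in set 1, and 369, 252 and 470 TPM in set 2. ESRRA and ESRRG themselves differed by -1.17 ± 0.14 and 1.55 ± 0.19. The smallest adjusted p was 0.209 (limma, 0 genes past the threshold; 1603 at an unadjusted p under 0.05; 0 genes also with the robust form). Without the control library of set 1 or of set 2, 1 gene passed, and EPAS1 then had an adjusted p of 0.0362 and 0.0198.

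Of the gene lists, 10 differed between ERRα and ERRγ siRNA by camera, and 0 did with an estimated correlation (smallest adjusted p = 0.941). G2 and M phase genes differed by a median of -0.35 (camera adjusted p = 5.96e-12), cytosolic ribosomal proteins by 0.13 (3.29e-10), S phase genes by -0.21 (5.86e-05) and p53 targets by 0.21 (5.86e-05). The S phase difference was lost without the ERRγ library of set 2 (camera adjusted p = 0.549, median -0.13), and the median of the p53 targets was then 0.12 (camera adjusted p = 0.00357). With the trend of gene length, GC content and expression level removed, the S phase difference was -0.036 in set 1 and -0.27 in set 2.

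The double knockdown was compared with the sum of the single ones. Among the genes with the smallest p were SEC14L1 (-1.27 ± 0.17), the phosphatase SSU72 (-0.999 ± 0.137), the cytochrome oxidase assembly factor COX11 (-1.56 ± 0.27) and MAGEA6 (1.28 ± 0.20). The abundant chromatin protein PTMA (-1.32 ± 0.20) was, like SEC14L1, a gene in which the double knockdown library stood apart. No gene passed (limma, smallest adjusted p = 1, 0 genes; 340 at an unadjusted p under 0.05; 0 genes also with the robust form; 1 gene without the control library of set 1). By camera, 3 lists departed from the sum: fatty acid synthesis by 0.17 (adjusted p = 0.0129), p53 targets by -0.13 (0.0335) and TCA cycle genes by 0.15 (0.0483), with adjusted p = 0.941 with an estimated correlation. Leave-outs ended these calls: fatty acid synthesis without the control (camera adjusted p = 0.205), ERRα (0.0674) or ERRγ library (0.0791) of set 1 and the ERRα library of set 2 (0.0772), p53 targets without the control (0.115) or ERRα library (0.13) of set 1 and any library of set 2 other than the double knockdown (0.106 to 0.227), and TCA cycle genes without any of the 6 (0.075 to 0.24). The p53 median was -0.045 without the ERRα library of set 2, and that of fatty acid synthesis was 0.27. The TCA cycle call was also lost with a pseudocount of 5 (0.0594), median centring (0.0818), rescaling without ribosomal protein genes (0.0742) and quantile normalization (0.209, median 0.076). With no set term all 3 calls were lost (camera adjusted p = 0.252, 0.684 and 0.188), and the medians were 0.498 for fatty acid synthesis, 0.425 for p53 targets, which turned, and 0.333 for TCA cycle genes, where the median of all genes was 0.327.

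How far the sets gave the same fold changes was measured across genes. ERRγ fold changes correlated with r = 0.24 between sets (Spearman 0.25), and ERRα fold changes with r = 0.12 (Spearman 0.17). For ERRα with ERRγ fold changes across sets, r was 0.01 for ERRα in set 1 with ERRγ in set 2. It was 0.063 for ERRγ in set 1 with ERRα in set 2, and the mean of both was 0.036. At least 2-fold in both sets with ERRγ siRNA, 6 genes were higher and 19 lower, where 1.9 and 1.9 are expected of independent lists, and 4 changed in opposite directions. With ERRα siRNA, 4 genes were higher and 3 lower (0.6 and 0.7 expected), and 10 were opposite (1.2 expected). ERRα siRNA in set 1 with ERRγ siRNA in set 2 gave similar numbers, 3 higher, 4 lower and 10 opposite (0.6, 1.3 and 1.7 expected). These overlaps were counted after the data were seen. The double knockdown fold changes correlated with r = 0.21 with the sum of the single ones in set 1. Taken alone, the slope was 0.173 on the ERRγ and 0.079 on the ERRα fold changes of set 1. With both in the model it was 0.20 and -0.057. Those fold changes share a control, which can shift both slopes, so the negative one does not show that an ERRα part was absent. Within set 2, where all share a control, the slopes with both in the model were 0.553 on ERRγ and 0.304 on ERRα. Within set 2, where the control is shared, the double knockdown correlated with r = 0.68 with ERRγ and 0.50 with ERRα fold changes, against 0.50 in simulated unchanged groups; the covariances were 0.0687 and 0.0417 against a simulated 0.0352. Within a set, ERRα and ERRγ fold changes correlated with r = 0.51 in set 1 and 0.44 in set 2, with covariances of 0.0773 and 0.0371 beside the same simulated values. With 1 control per set the controls could not be split, so part of each of these values may come from the shared control.

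**Figure D4:**
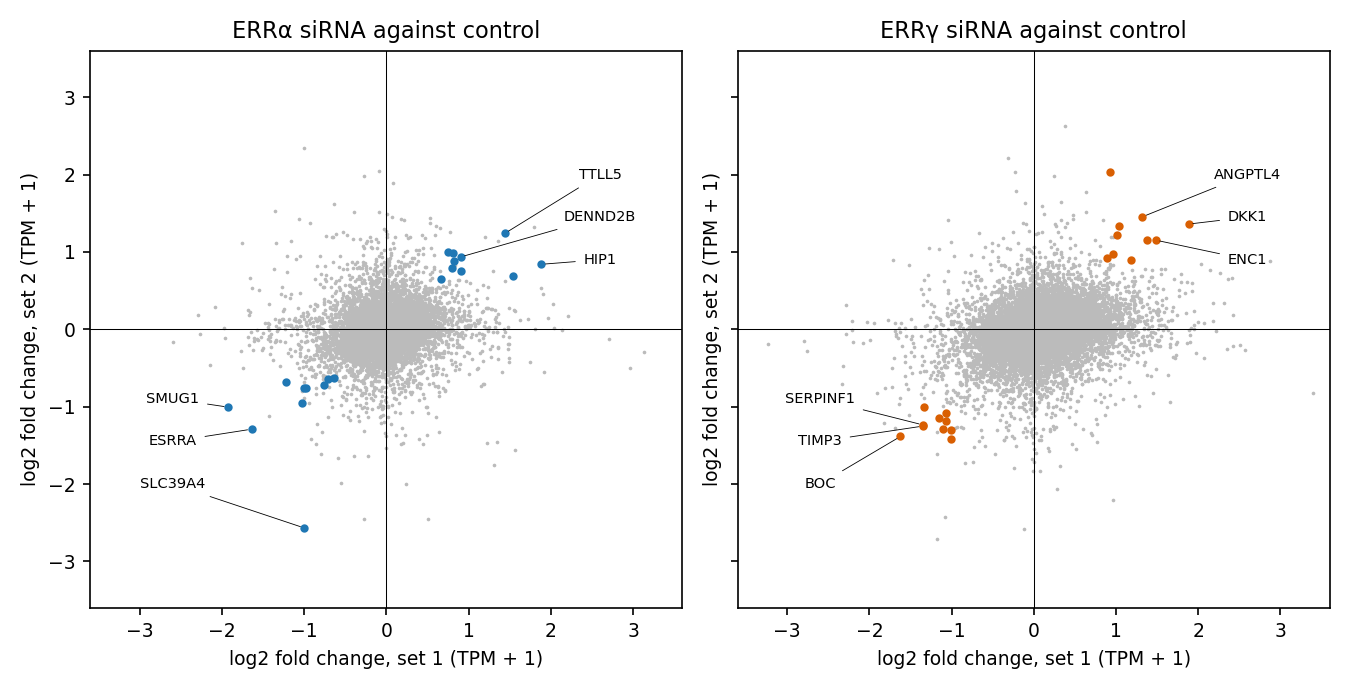
Log2 fold change of each tested gene in set 1 (horizontal) and set 2 (vertical), on the log2(TPM + 1) scale, for ERRα siRNA (left) and ERRγ siRNA (right); coloured points are the 20 genes picked by rule for each knockdown. ESRRA lies at -1.64 and -1.29 in the left panel, and DKK1 at 1.89 and 1.36 in the right panel.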

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

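The tests of the control libraries and of the S phase genes were chosen only after the result was seen; the other tests below were written down before. Each gene list here was picked out because its difference between ERRα and ERRγ siRNA passed camera's test of that difference at the preset correlation; none passed with an estimated correlation (smallest adjusted p = 0.941).

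G2 and M phase genes differed between the knockdowns by a median of -0.352 (-0.335 in set 1, -0.311 in set 2; camera adjusted p = 5.96e-12) and S phase genes by -0.212 (-0.16 and -0.283; 5.86e-05; -0.126 and lost without ERRγ replicate 2, 0.549). A control library low in cell cycle transcripts would raise both knockdowns alike and does not enter the difference between them. Such a control could not by itself make the difference of -0.311 or further from 0 in each set. The list was picked by this same difference, so its distance from 0 is no independent test. With 1 library per condition and set, a low control could still hold part of the rise with ERRγ siRNA. With the trend of fold change on gene length, GC content and expression level removed, the G2 and M phase median with ERRγ siRNA went from 0.287 (bootstrap SE 0.06) to 0.177 (SE 0.034) in set 1 and from 0.407 to 0.408 (SE 0.024) in set 2, so this trend was not the whole cause, though in set 1 it could hold part of the shift. For S phase genes the set 1 median went from 0.13 (SE 0.07) to 0.074 (SE 0.055), which decides nothing. The set 2 median went from 0.332 to 0.309 (SE 0.037), so the fitted trend was not the whole cause there. These bootstrap SEs come from resampling the genes of a list. They do not measure the spread between libraries or cultures. The biological explanation that the design offers, a response to loss of ERRγ, remains open. With 1 library per condition and set, a difference in culture density or growth between wells could not be told from it. Neither could another effect of the siRNA.

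Cytosolic ribosomal protein genes differed between the knockdowns by 0.134 (0.182 in set 1, 0.094 in set 2; camera adjusted p = 3.29e-10) and mitochondrial ribosome genes by 0.072 (0.12 and 0.058; 0.00588). The mitochondrial difference was lost without ERRα replicate 1 (0.063; adjusted p = 0.154) and without ERRγ replicate 1 (0.043; 0.685), and was 0.109 without ERRγ replicate 2, 0.131 with equal medians, 0.135 rescaled without ribosomal protein genes and 0.12 with quantile normalization. With the trend of length, GC content and expression level removed, the cytosolic median with ERRγ siRNA stayed below 0 in both sets. It was -0.187 in set 1 (before, -0.178) and -0.221 in set 2 (before, -0.089). The trend was fitted to the other genes and extended to these abundant ones, where its fit could not be checked. The removal therefore does not decide whether a trend with abundance was the whole cause. Quantile normalization left a median of -0.056, so the size of the shift may depend on the scaling of abundant genes. A response to ERRγ loss was not told apart from other differences between these libraries.

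In some abundant genes a single library lay at least 2-fold from every other library of its set while those lay close together, a definition chosen after the data were seen. Of 5990 genes at a mean of at least 20 TPM, 79 had such a library, 42 of them the ERRγ library of set 1. No gene had it in the same condition of both sets. In set 2 the ERRα library stood apart in 0 genes and the ERRγ library in 3, so the absence of repeats says nothing. Few reads behind a value could be a cause at low expression, but the share at 100 TPM or more was 0.384 times (95% interval 0.206 to 0.606) that at 5 to 20 TPM, which decides nothing for the abundant genes, and an overlap of exons with other genes was 6.7 percentage points more frequent (-4.3 to 17.5), which decides nothing either. A gene with such a library had the higher ratio of longest to shortest annotated transcript with probability 0.595 (0.531 to 0.657), so reads assigned to transcripts of unequal length may contribute, as a candidate explanation. No biological explanation was tested.

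The remaining lists were picked out in the same way. p53 target genes differed by 0.206 (0.13 in set 1, 0.251 in set 2; camera adjusted p = 5.86e-05), and by 0.121 without ERRγ replicate 2 (0.00357). NRF2 antioxidant genes differed by 0.185 (0.191 and 0.107; 0.00066), and by 0.093 without ERRγ replicate 1 (0.211). Genes of the unfolded protein response differed by -0.198 (-0.39 and -0.064; 0.00588), and by -0.087 without ERRα replicate 1 (0.154) and -0.092 without ERRγ replicate 1 (0.534), -0.339 and -0.374 without ERRα and ERRγ replicate 2, and -0.127 with quantile normalization. Subunits of complexes II to IV with cytochrome c differed by 0.109 (0.163 and 0.019; 0.00677), and by 0.067 (0.27) and 0.042 (0.604) without ERRα and ERRγ replicate 1, 0.171 without ERRα replicate 2, 0.168 with equal medians and 0.173 rescaled without ribosomal protein genes. Genes of the integrated stress response differed by 0.064, with opposite signs in the sets (0.2 and -0.067; 0.0245), and by 0.023 (0.555) and -0.045 (0.983) without ERRα and ERRγ replicate 1, 0.156 and 0.169 without ERRα and ERRγ replicate 2, and 0.121 to 0.127 with equal medians, rescaling or quantile normalization; the call was also lost with no set term (0.0789). Genes of the siRNA machinery differed by -0.218 (-0.366 and -0.042; 0.0483), and by -0.026 (0.289) and -0.128 (0.685) without ERRα and ERRγ replicate 1, and -0.357 (0.0286) and -0.352 (0.00947) without ERRα and ERRγ replicate 2; the call was also lost with a pseudocount of 5 (0.059), at least 5 TPM in 2 libraries (0.0703), quantile normalization (0.0533) and no set term (0.142).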

How the results depend on the processing

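The table unit keeps no read counts, so what sequencing depth limits could not be measured. Each condition had 1 library per set, so leaving a library out left a group with a lone library, assumed to vary like the others. All alternatives were chosen before the data were examined, except the robust fit. Of 2654 values of single genes, 2641 kept direction and side of the threshold, 4 became stronger and 9 reversed. No gene passed in the main fit, so keeping the side only means staying short of the threshold, and no call was there to lose. Apart from the targeted receptors, these genes were named for a large change or a small p. Those ranked for a single knockdown also had the same sign in both sets. The share of kept values is therefore no independent measure of robustness. For lists, direction is that of camera, which compares a list with all other genes. By it, of 329 values of knockdown lists, 312 were kept, 17 became weaker and 0 reversed; of 217 values of lists between knockdowns, 178 were kept, 38 became weaker and 1 reversed. At the preset correlation, several calls stayed past the threshold wherever they had a value. These were G2 and M phase genes with ERRγ siRNA, in the double knockdown and between the knockdowns, and p53 targets with ERRα siRNA and between the knockdowns. The same held for histone genes in each knockdown, NRF2 genes with ERRγ siRNA and cytosolic ribosomal proteins between the knockdowns. It also held for S phase, complex I, mitochondrial ribosome and retinoic acid genes in the double knockdown. The ribosomal protein list has no value under the rescaling without its genes.

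Across leave-outs, genes past the threshold ranged from 0 to 9 with ERRα siRNA, 0 to 13 with ERRγ siRNA, 0 to 2 in the double knockdown, 0 to 1 between the knockdowns and 0 to 1 against the sum, the highest for both single knockdowns without control replicate 2. Lists past the threshold ranged from 11 (without the double knockdown library, where 68 tests remain) to 26 (without control replicate 2). The count of lists was 0 with an estimated correlation and 0 by fry. LMNA in the double knockdown passed without control replicate 1 (-2.617) and 2 (-4.217), as did EPAS1 between the knockdowns (-1.848 in both); in LMNA the control of set 1 and the double knockdown library each stood apart from their set.

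The correlation between sets was 0.081 for ERRα, 0.201 for ERRγ and 0.15 for the double with the single knockdowns at a pseudocount of 0.1; 0.14, 0.271 and 0.251 at a pseudocount of 5; and 0.149, 0.261 and 0.249 with at least 5 TPM in 2 libraries. By Spearman it was 0.174 for ERRα and 0.252 for the double knockdown. With no set term, NDUFB5 (0.126), NDUFS1 (0.214), RPL34 (0.381) and TXNRD1 (0.182) reversed in the double knockdown, where the median of all genes moved to 0.35 because the lone library was then compared with both controls. The medians of complex I (0.143), cytosolic ribosomal protein (0.172), mitochondrial ribosome (0.112) and ATP synthase genes (0.051) also changed sign there, as did p53 targets against the sum (0.425, with 0.327 for all genes), while their direction by camera did not. Over leave-outs, reversals gave ranges of -1.304 to 0.398 for PGS1 and -0.016 to 0.91 for ATP5PD in the double knockdown, -0.043 to 0.867 for DNAJB9 and -1.849 to 0.092 for MRPL23 with ERRγ siRNA, and -0.045 to 0.169 for the integrated stress response between the knockdowns; the cause was not tested.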

Other observations

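None of the genes in this part was chosen by the rule for named genes unless the text above names it; they were picked after their values were seen, and the comparison of set levels was chosen then too.

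Several single genes differed in the same direction with ERRγ siRNA in both sets, and none of them passed the threshold. The retinoic acid receptor RARB was 1.43 TPM in the control and 0.0731 TPM with ERRγ siRNA in set 1, and 2.45 and 0.125 TPM in set 2 (fitted -1.40 ± 0.21; limma, adjusted p = 0.27). CRABP2 was 105 and 31.2 TPM in set 1 and 159 and 94.2 TPM in set 2. The list of retinoic acid response genes did not pass with ERRγ siRNA (median -0.092, mean -0.31; camera adjusted p = 0.147). CHRNA3 was 81.5 and 142 TPM in set 1 and 72.1 and 130 TPM in set 2 (fitted 0.81 ± 0.09; limma, adjusted p = 0.258). The noradrenaline transporter SLC6A2 was 67.0 and 157 TPM in set 1 and 140 and 181 TPM in set 2, and the dopamine hydroxylase DBH differed by 0.74 and 0.37; the ERRγ library of set 1 was one that stood apart for SLC6A2. The list of catecholamine synthesis and storage genes did not pass (medians 0.28 and -0.029, 6 of 17 higher in both sets; camera adjusted p = 0.442), nor did the noradrenergic regulators (camera adjusted p = 0.3). The calcium channel CACNA1G differed by -1.51 and -1.11. The imprinted gene DLK1 was 403 and 722 TPM in set 1 and 25.3 and 69.1 TPM in set 2 (fitted 1.13 ± 0.15; limma, adjusted p = 0.264), and RTL1, which lies near it, was 541 and 896 TPM in set 1 and 41.4 and 78.0 TPM in set 2. RHOA, lower with ERRα siRNA in both sets, was 467 TPM in the double knockdown against 369 TPM in its control.

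The sets differed in level, which was described and not tested because the tables were made separately; differences between the cells and between the measurements cannot be told apart. In every library of set 2, 88 genes were at least 4-fold higher than in every library of set 1, and 9 were higher in set 1. IGFBP3 was 5.43 TPM in the control of set 1 and 572 TPM in that of set 2, PTX3 0.948 and 77.1 TPM, LUM 1.56 and 38.3 TPM, and IGFBP5 21.3 and 430 TPM. IGF2 was 186 TPM in the control of set 1 and 6.06 TPM in that of set 2. Fibroblast markers were lower in the control of set 1 than of set 2 by a median of -1.56 (9 of 10 lower; percentile 0.1 among 10000 random lists), and mesenchymal neuroblastoma markers by -1.12 (18 of 19 lower; percentile 0.88), against a median of -0.634 over all genes. Cytosolic ribosomal protein genes also differed (median -0.465, percentile 0.0 among matched random lists), with RPL7 at 152 TPM in the control of set 1 and 1489 TPM in that of set 2. With the knockdowns, neither the fibroblast nor the mesenchymal list passed (camera adjusted p of at least 0.215).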
